A study of Danio rerio with 19 samples.

How the data were processed

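DNA methylation was measured by targeted amplicon bisulfite sequencing in the gonads of 19 zebrafish of the AB strain, 9 with ovaries and 10 with testes, all 90 days old and kept under control conditions, per the labels. Bisulfite treatment turns unmethylated cytosine into uracil, which is read as T, so the share of C among the reads at a CpG gives its methylation level. Per the labels' protocols, DNA was extracted with phenol and chloroform, 1000 ng per fish was converted, and the libraries were indexed with a Nextera XT kit and sequenced on a MiSeq. The submitters' processing notes name Trim Galore 0.4.5, FastQC 0.11.6, Bowtie2, Bismark and the genome build GRCz11.

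The deposited files give, per fish and cytosine position, the count of methylated and the count of unmethylated reads, with no normalization. They also give the percent methylated, which the authors computed from these counts: the deposited percent equals methylated reads over all reads in all 4476 combinations of position and fish. A table of the whole series holds the same 4476 combinations with identical counts. No filter on coverage and no conversion control are described in the sources used here. The reads carry no molecular identifiers that the sources mention, so counts of reads are not counts of molecules, and intervals from them cover counting error only.

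Each fish was 1 replicate and its sex came from the source label. Total methylation calls per fish ran from 488594 (ovary 2) to 2235082 (ovary 18). A position entered a fish at a coverage of 10 reads or more and was tested where at least 5 ovaries and 5 testes had it. Of 470 positions, 150 were tested and 320 left out; the tested ones held 99.9% of all calls. Tested positions less than 1000 bp apart formed a region, which gave 9 regions. A fish entered a region test if it had at least 50% of the region's CpGs. Among the 150 positions, 11 had a median coverage under 10% of their region's and mean levels of at most 1.04% in either sex. They are counted in the totals, and region means are given without them where it matters.

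Per CpG, the statistic was the difference between the sexes in the weighted mean level, with beta-binomial (Williams) weights that allow for spread between fish beyond read counting. Its two-sided p came from exact permutation of the sex labels over all 92378 splits of the 19 fish, or fewer where fish lacked the CpG. Adjustment was by Benjamini-Hochberg over the 150 CpGs, with a threshold of 0.05. Per region, the mean level over its CpGs was taken in each fish and compared by a two-sided exact permutation test, adjusted over the 9 regions. With all 19 fish, the smallest p these permutations can give is 1.08e-05. Spread between fish was compared by exact permutation of the absolute deviations from the own sex's median. Depth was compared by exact permutation on log10 coverage, adjusted over 10 measures. Correlations between regions were computed within a sex only, with exact permutation for fewer than 10 fish and 100000 resamples for 10. Fish were also compared in pairs, region by region, by a chi-square of their counts per CpG. A low value, with a chi-square p of 0.05 or more, marks fish that agree within sampling noise. The p takes the CpGs of a region as independent. CpGs on the same reads may vary together, so calls just beyond noise are not firm. Over all regions together no 2 of the 19 fish agreed: the lowest chi-square per CpG was 18.2 (testis 7 and testis 12).

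The CpG test was checked on simulated beta-binomial counts at the real coverages, over 5 runs of 150 CpGs with an overdispersion of 0.02. For ovary against testis it called 63% of CpGs with a true difference of 5 points, 97% at 10 points and 100% at 20 points. It called 1.56% of unchanged CpGs. Within a sex, the real CpGs past the threshold had a median overdispersion of 0.0464 in ovaries and 0.0181 in testes, with 90th percentiles of 0.240 and 0.316; without the first chromosome 5 region the medians were 0.0274 and 0.00315. Simulated at 0.2, near the upper end, the test called 19%, 33% and 64% of CpGs at those sizes and 0.222% of unchanged ones. In both simulations the base levels were kept off the extremes and each CpG was drawn independently. These rates therefore do not cover regions with hardly any methylation, very high levels, or CpGs of a region that vary together. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

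The tests, the alternatives and the rule for named CpGs were fixed before the data were examined, except where the closing parts say otherwise; the comparison of fish in pairs and of level with depth was added after the data had been seen. The rule names every region and, in each, up to 5 CpGs past the threshold with the smallest adjusted p, ties going to the larger difference; a region with none past it is given by its CpG with the largest difference. Alternatives were coverage minimums of 5, 30 and 100 reads, other weights, Fisher's exact test on pooled reads, limma, at least 8 fish per sex, adjustment within regions, summed strands, medians or pooled reads per region, and leaving out each fish. An annotation of the GRCz11 build was not used here. Regions are therefore named by chromosome, and the rule that would have named them by gene, with its gene lists, was not applied. The names il1b and casp9 rest on the series title together with the chromosome these genes lie on (10 and 23), each of which carried 1 tested region; no file pairs a region with a gene. Whether a region lies in a promoter, exon or intron was not determined.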

Results

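CpG methylation was compared between ovaries (n = 9 fish) and testes (n = 10 fish) of adult zebrafish in 9 regions. Total calls per fish had a median of 1172304 in ovaries and 1387234 in testes and did not differ between the sexes (ratio of geometric means 0.866, exact permutation p = 0.453). The median over fish of the coverage per CpG was at least 3233.5 reads in 8 regions and 13 reads in the chromosome 7 region. Coordinates are those of GRCz11.

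The first question, taken from the series title, was which of these regions are methylated differently in the gonads of the sexes. Of 150 CpGs tested, 71 differed, 35 with less and 36 with more methylation in ovaries. The chromosome 10, 18 and 19 regions were less methylated in ovaries, and the chromosome 24 region was more methylated in ovaries. In these 4 regions every ovary lay outside the range of all testes. The first chromosome 5 region contributed 24 of the 36 CpGs that were higher in ovaries. There the fish were not taken as independent, because many agreed in pairs, as described below. Without this region 47 of 126 CpGs differed, 12 of them higher in ovaries. At 34 CpGs the sexes did not overlap, which chance gives at 0.00217% of CpGs.

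**Figure D1:**
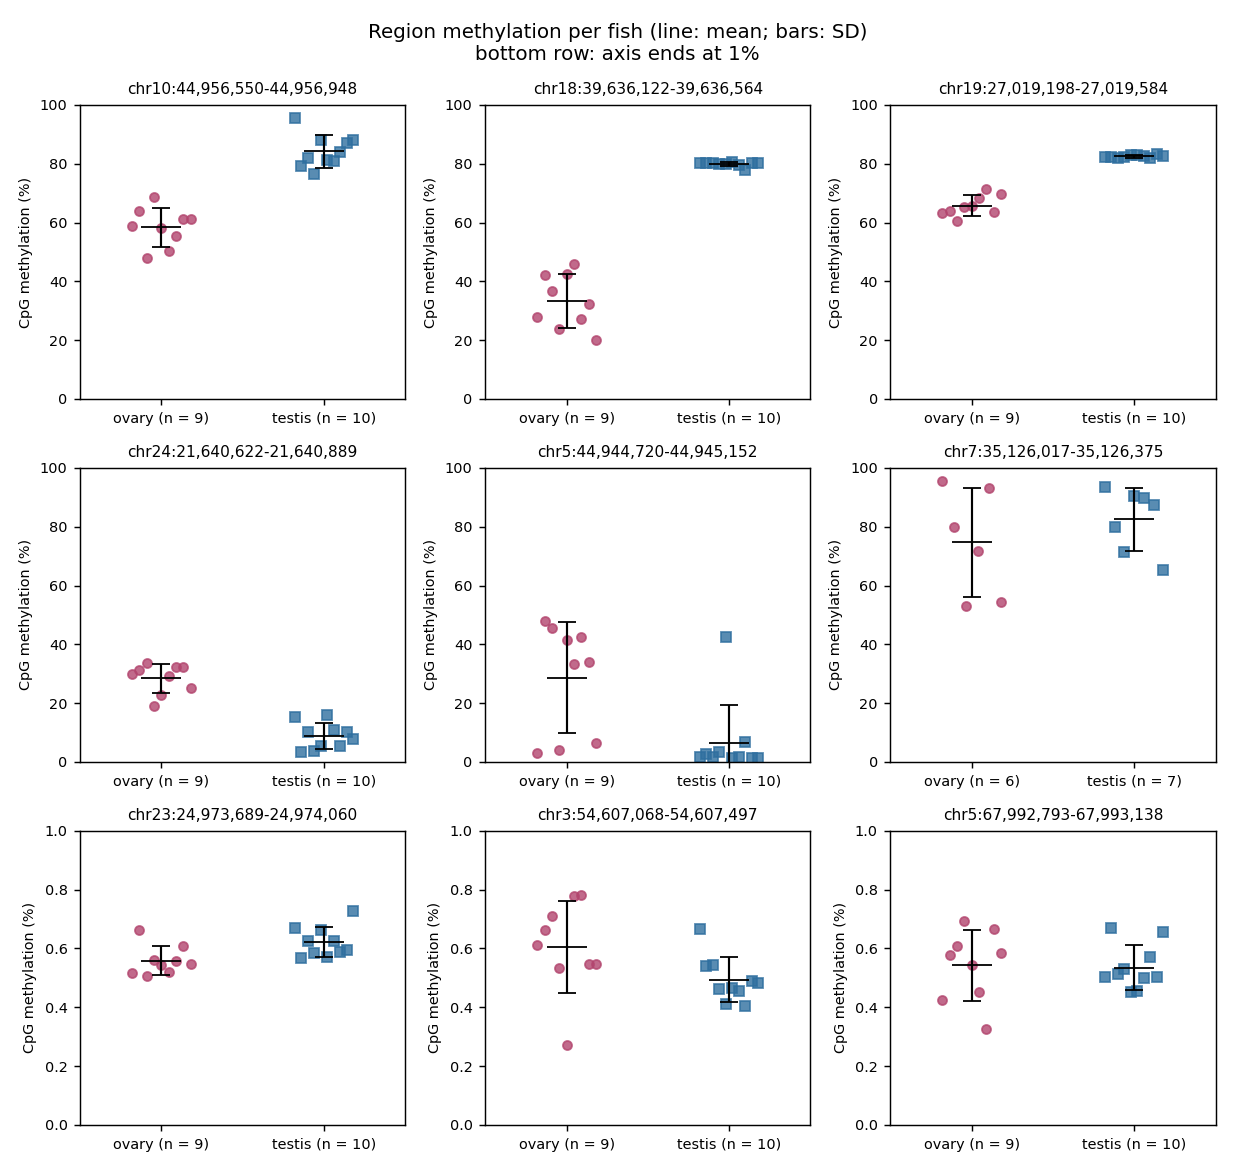
Mean CpG methylation of each region in percent, with 1 point per fish, ovaries as circles and testes as squares; the horizontal line is the mean and the bars are the SD over fish. The sexes are fully apart in the chromosome 10, 18, 19 and 24 regions, and the bottom row, whose axis ends at 1%, shows regions with levels under 1% in every fish.

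The chromosome 10 region (44956550 to 44956948), the only one on the chromosome of il1b, was less methylated in ovaries. il1b encodes interleukin-1 beta, a pro-inflammatory cytokine. The region mean was 58.4% ± 6.54 (SD, n = 9) in ovaries and 84.3% ± 5.56 (SD, n = 10) in testes. The highest ovary stood at 68.9% and the lowest testis at 76.4%. Without 1 position of very low coverage the means were 61.7% ± 5.23 (SD, n = 9) and 89.7% ± 4.08 (SD, n = 10), and the lowest testis stood at 84.0%. The exact permutation p was 1.08e-05, the smallest these permutations can give (adjusted p = 2.44e-05). Of 10 CpGs, 8 were lower in ovaries and none higher. The widest gap was at 44956589, with 40.8% ± 10.2 (SD, n = 9) in ovaries against 91.2% ± 4.04 (SD, n = 10) in testes, followed by 44956563 (47.1% against 91.7%), 44956550 (57.0% against 93.1%), 44956574 (59.4% against 92.8%) and 44956641 (66.1% against 93.4%). Each of these 5 CpGs had an adjusted p of 4.92e-05 by exact permutation and a coverage of at least 955 reads in every fish. The sexes did not separate at 44956872, which had 60.3% ± 17.998 (SD, n = 9) in ovaries and 61.2% ± 21.6 (SD, n = 10) in testes (exact permutation p = 0.919). In this region testis 9 and testis 19 agreed within sampling noise (chi-square per CpG 0.422), and counted as 1 sample they left a difference of 25.5 points with an adjusted p of 9.26e-05 by exact permutation.

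The chromosome 18 region (39636122 to 39636564) showed the widest difference of all regions. Its mean was 33.2% ± 9.19 (SD, n = 9) in ovaries and 79.9% ± 0.750 (SD, n = 10) in testes (exact permutation p = 1.08e-05, adjusted p = 2.44e-05). Without 3 positions of very low coverage the means were 37.5% ± 10.6 (SD, n = 9) and 95.9% ± 0.894 (SD, n = 10). All 15 of the remaining CpGs were lower in ovaries and separated the sexes without overlap. Ovary levels were near 35% and testis levels near 95% at the CpGs with the widest gaps: 39636210 (34.4% against 95.7%), 39636523 (35.1% against 95.8%), 39636171 (35.4% against 96.1%), 39636218 (35.4% against 95.7%) and 39636412 (35.2% against 94.9%), each with an adjusted p of 4.92e-05 by exact permutation. Ovaries also had fewer reads here, with a geometric mean coverage of 4460 against 18403 in testes (ratio 0.242, exact permutation p = 0.000238, adjusted p = 0.00238). Across the 9 ovaries no relation of level with depth was found (r = -0.153, exact permutation p = 0.695, rho = -0.0333, exact permutation p = 0.948, r = 0.370 without the 2 fish farthest from the median depth, adjusted p = 0.812 over 14 such relations). With 9 fish a relation is not excluded, and relations within ovaries do not address the depth gap between the sexes. Of the 14 relations the lowest p was that of chromosome 10 in testes (r = -0.630, permutation p = 0.0470, adjusted p = 0.657).

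The chromosome 19 region (27019198 to 27019584) was also less methylated in ovaries, at 65.8% ± 3.47 (SD, n = 9) against 82.5% ± 0.505 (SD, n = 10) in testes (exact permutation p = 1.08e-05, adjusted p = 2.44e-05). Of its 7 CpGs, 6 were lower in ovaries. The difference was widest in the middle of the region, at 27019461, with 53.1% ± 7.06 (SD, n = 9) against 94.0% ± 1.25 (SD, n = 10). It was smaller at 27019198 (73.7% against 97.2%), 27019279 (73.6% against 97.0%), 27019544 (80.8% against 96.3%) and 27019548 (82.8% against 95.2%). All 5 had an adjusted p of 4.92e-05 by exact permutation. The remaining CpG, 27019282, lay 3 bp from a highly methylated neighbour and was at 2.93% ± 6.65 (SD, n = 9) in ovaries and 0.460% ± 0.233 (SD, n = 10) in testes. Coverage was again lower in ovaries (geometric mean 3220 against 13008, ratio 0.248, exact permutation p = 0.00163, adjusted p = 0.00817). Across ovaries no relation of level with depth was found, with the same limits (r = -0.114, exact permutation p = 0.777, rho = -0.0333, exact permutation p = 0.948, r = 0.494 without the 2 farthest fish, adjusted p = 0.837).

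The chromosome 24 region (21640622 to 21640889) differed the other way. Its mean was 28.4% ± 5.01 (SD, n = 9) in ovaries and 8.80% ± 4.45 (SD, n = 10) in testes (exact permutation p = 1.08e-05, adjusted p = 2.44e-05). The lowest ovary stood at 18.9% and the highest testis at 15.9%. Of 13 CpGs, 12 were higher in ovaries. The CpGs named by the rule were 21640685 (22.3% ± 7.20 against 2.70% ± 0.946), 21640721 (21.3% ± 4.19 against 2.92% ± 1.14), 21640703 (16.3% ± 5.01 against 2.001% ± 0.659), 21640873 (16.3% ± 4.07 against 2.12% ± 0.822) and 21640622 (15.4% ± 3.63 against 3.15% ± 1.56), as mean and SD of 9 ovaries against 10 testes, each with an adjusted p of 4.92e-05 by exact permutation. The widest differences were at 21640648 (64.0% against 17.8%, adjusted p = 9.02e-05 by exact permutation, without overlap), 21640666 (61.0% against 20.3%, adjusted p = 0.000132) and 21640651 (47.4% against 12.5%, adjusted p = 0.000541). At 21640811 the sexes overlapped, with 39.6% ± 15.2 (SD, n = 9) in ovaries and 32.3% ± 20.4 (SD, n = 10) in testes (exact permutation p = 0.374).

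**Figure D2:**
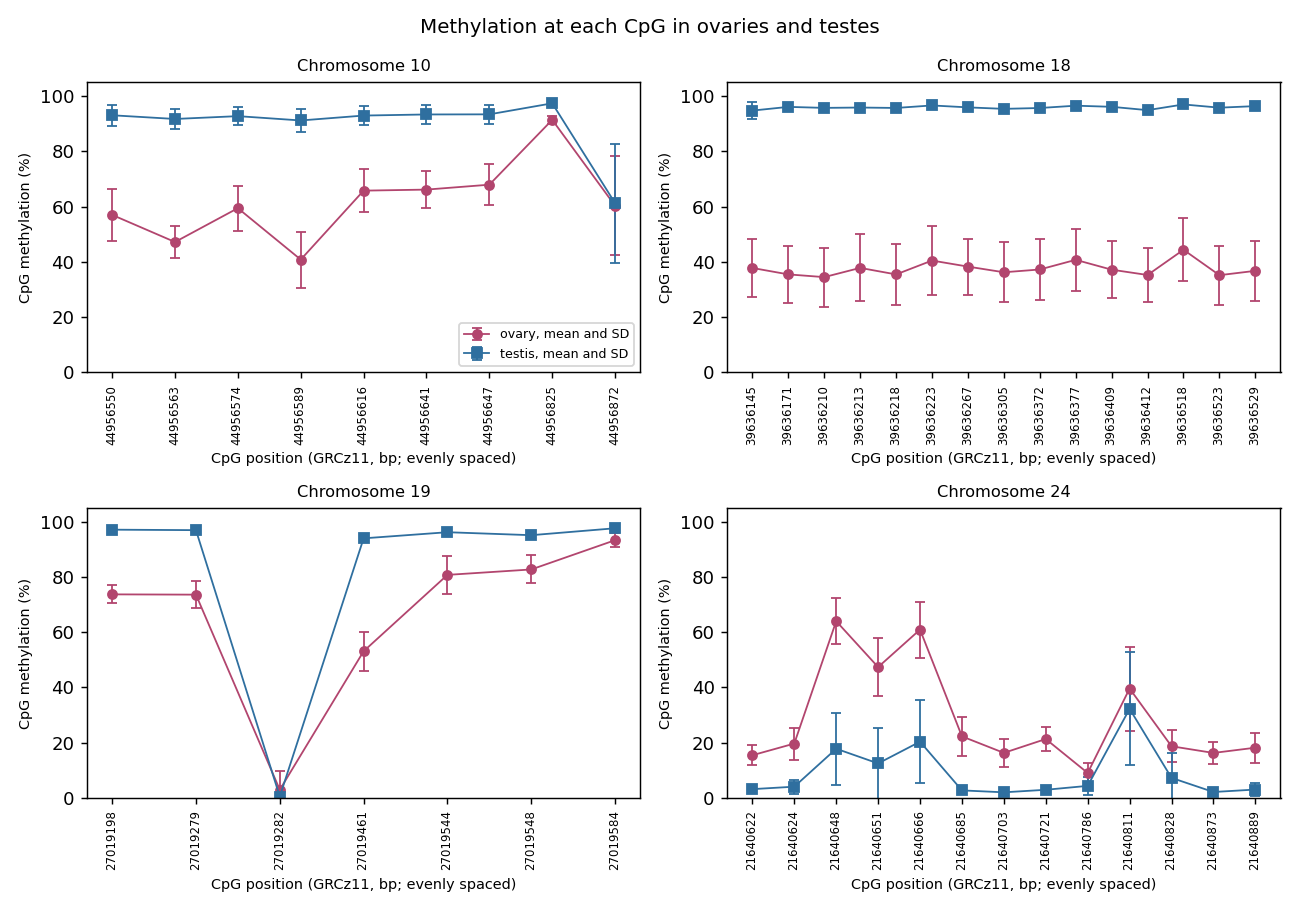
Mean methylation in percent at each CpG of the chromosome 10, 18, 19 and 24 regions, ovaries as circles and testes as squares, with bars for the SD over fish; CpGs are evenly spaced in order of position and those of very low coverage are left out. Testes lie above 90% at most CpGs of the chromosome 10, 18 and 19 regions, and the sexes meet at 44956872, 27019282 and 21640811.

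The first chromosome 5 region (44944720 to 44945152) had a mean of 28.7% ± 18.8 (SD, n = 9) in ovaries and 6.43% ± 12.8 (SD, n = 10) in testes (exact permutation p = 0.00822, adjusted p = 0.0148), and all 24 CpGs were higher in ovaries. Ovaries 2, 5, 11, 13, 15 and 17 had 48.1%, 45.5%, 41.6%, 33.4%, 42.4% and 34.0%, while ovaries 1, 6 and 18 had 2.87%, 3.95% and 6.44%. Testis 9 had 42.5%, and the other 9 testes lay between 1.23% and 6.86%. Depth split the ovaries in the same way. Median coverage was 93 (ovary 5) to 2330 reads (ovary 15) in those with high levels. It was 3687 (ovary 1) to 14578.5 reads (ovary 18) in those with low levels. Testes did not split so, since testis 9 had 2725.5 reads and testis 19, at 1.24%, had 433. A relation of level with depth was not tested in this region. The 5 CpGs named by the rule were 44945108 (58.3% ± 38.4 against 11.7% ± 23.8, adjusted p = 0.0130 by exact permutation), 44945105 (53.0% against 10.6%), 44944888 (18.3% against 3.67%), 44945118 (43.9% against 8.76%) and 44945152 (37.5% against 7.07%). With fish weighted by coverage none of the 5 passed: their differences fell to 14.9, 13.8, 4.998, 11.3 and 9.12 points, with adjusted p from 0.321 to 0.405 by exact permutation, and 44945152 also fell short at a coverage minimum of 100 (27.3 points, adjusted p = 0.0528) and without ovary 2, 5, 11 or 15 (adjusted p 0.0548 to 0.0584). The fish were not taken as independent here, because many agreed in pairs. In this region 18 of the 19 fish formed 9 pairs in which each fish was nearest to the other, and in 8 pairs the counts agreed within sampling noise, with a chi-square per CpG between 0.427 (ovary 13 and ovary 17) and 1.31 (testis 14 and ovary 18). Of these 8 pairs, 3 joined an ovary with a testis: ovary 1 with testis 4, ovary 11 with testis 9 and ovary 18 with testis 14. Ovaries 2 and 5 agreed at only 165 and 93 reads, with a root mean square difference of 4.57 points. Of all 171 pairs of fish, 11 agreed within noise here. The 3 others joined testis 19, at the lower coverage of 433 reads, with testes 3, 7 and 10 (1.24 to 1.27), so the agreement of testes at low levels is not exclusive to pairs. Chromosome 3 also had 11 of 171 pairs within noise, but in none of them did both fish have a median coverage of 50 reads or more. In the first chromosome 5 region all 11 pairs had that coverage. Fish nearest to each other were also found in other regions, with 7 pairs on chromosome 10. Of those, 1 agreed within noise, as did the only such pair on chromosome 3, and none did in the other regions compared. In those other regions the lowest value was 1.77, for ovary 5 and ovary 17 on chromosome 18 (chi-square p = 0.0331). That lies close to the bound, and the test takes CpGs as independent, so this call is not firm. In the other regions the 9 pairs were farther apart, though some stayed near: the lowest chi-square per CpG was 1.86 on chromosome 3 (testis 14 and ovary 18, the former at 19 reads), 3.77 in the second chromosome 5 region and 3.90 on chromosome 23 (testis 3 and testis 7), 4.19 on chromosome 10 (testis 10 and testis 12), 6.97 on chromosome 18 (testis 16 and testis 19), 12.6 on chromosome 19 and 37.8 on chromosome 24. With the 5 pairs of the same sex counted as 1 sample each and the 3 mixed pairs left out, ovaries had 31.7% ± 19.3 (SD, n = 4) and testes 1.95% ± 0.973 (SD, n = 4), with an exact permutation p of 0.0286 (adjusted p = 0.0429). With the ninth pair, ovary 6 and testis 8, also left out, 3 samples per sex remained and the exact permutation p was 0.1, the smallest that design can give. Mixed pairs were found by an ovary agreeing with a testis. Leaving out the 3 took away testis 9 and ovaries 1 and 18, and leaving out the ninth took away ovary 6. The levels of these fish go against the difference, so neither p tells whether the sexes differ here.

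**Figure D3:**
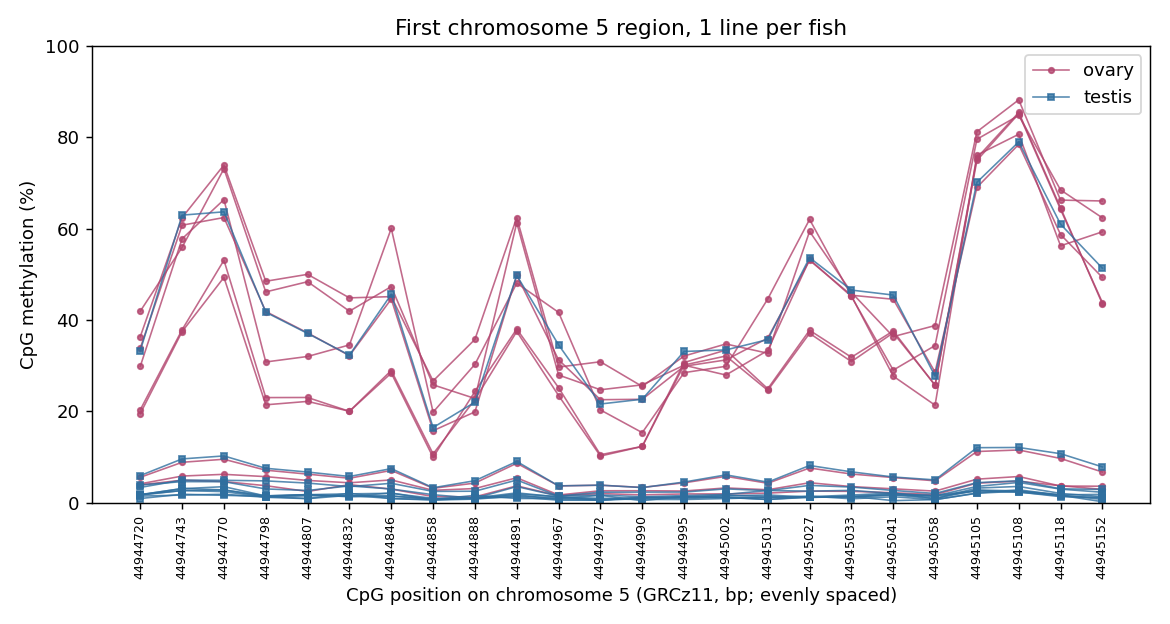
Methylation in percent at the 24 CpGs of the first chromosome 5 region, 1 line per fish, ovaries as circles and testes as squares, with CpGs evenly spaced in order of position. Testis 9, at a region mean of 42.5%, runs among the ovary lines, and ovaries 1, 6 and 18, at 2.87%, 3.95% and 6.44%, run among the testis lines.

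The chromosome 23 region (24973689 to 24974060), the only one on the chromosome of casp9, was almost unmethylated in both sexes. casp9 encodes caspase-9, an initiator protease of apoptosis. The mean was 0.558% ± 0.0496 (SD, n = 9) in ovaries and 0.621% ± 0.0518 (SD, n = 10) in testes, which fell by 0.0635 points from testis to ovary (exact permutation p = 0.0148, adjusted p = 0.0221). With the median over CpGs the difference was -0.296 points (0.315% against 0.611%, adjusted p = 0.000130 by exact permutation). Of 19 CpGs, 3 were lower in ovaries: 24973726 (0.337% ± 0.149 against 0.660% ± 0.0917, n = 9 and 10, adjusted p = 0.000342 by exact permutation), 24974054 (0.421% against 0.750%, adjusted p = 0.00380) and 24973728 (0.388% against 0.742%, adjusted p = 0.0219). Levels this low lie where unconverted cytosines and base errors also count as methylated, and no conversion control was analysed here.

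The chromosome 3 region (54607068 to 54607497) and the second chromosome 5 region (67992793 to 67993138) were also close to 0. Chromosome 3 had 0.605% ± 0.157 (SD, n = 9) in ovaries and 0.493% ± 0.0766 (SD, n = 10) in testes (exact permutation p = 0.0607, adjusted p = 0.0781). That call rested on single fish, since the difference passed without ovary 11 (0.154 points, adjusted p = 0.00481 by exact permutation) or without testis 3 (0.132 points, adjusted p = 0.0374). At its CpG 54607226 ovaries had 0.194% ± 0.119 (SD, n = 9) and testes 0.907% ± 1.54 (SD, n = 10), with an adjusted p of 0.0258 by exact permutation. The testis mean rests on testis 14, which had 5.26% from 19 reads; the other 9 testes averaged 0.423%, and the weighted difference was -0.271 points. The call was lost with adjustment within the region (adjusted p = 0.295 by exact permutation), coverage weights (0.113) and equal weights (0.0511), and narrowly without ovary 5, 11 or 15 (0.0528 to 0.0533). The second chromosome 5 region had 0.542% ± 0.120 (SD, n = 9) and 0.535% ± 0.0753 (SD, n = 10), which did not differ beyond the spread between fish (exact permutation p = 0.880). Its CpGs 67992853 (0.300% against 0.706%, adjusted p = 0.0180 by exact permutation) and 67993138 (0.341% against 0.684%, adjusted p = 0.0251) were lower in ovaries. Neither passed with adjustment within the region (adjusted p = 0.106 each by exact permutation), nor did 67992853 with fish weighted by coverage (0.2005). With the median over CpGs in place of the mean, the whole second chromosome 5 region was lower in ovaries (0.250% against 0.565%, adjusted p = 3.90e-05 by exact permutation).

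The chromosome 7 region (35126017 to 35126375) was highly methylated in both sexes, with 74.6% ± 18.4 (SD, n = 6) in ovaries and 82.5% ± 10.7 (SD, n = 7) in testes (exact permutation p = 0.351, adjusted p = 0.395). None of its 7 CpGs passed. Median coverage over fish was only 13 reads here, with 446 in the deepest fish, and whether this region was a target was not determined. The largest difference was at 35126295, with 65.0% ± 24.03 (SD, n = 6) against 77.9% ± 8.93 (SD, n = 7) (exact permutation p = 0.190, adjusted p = 0.331).

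In percent, ovaries varied more between fish than testes in 2 of the 9 regions. In the chromosome 18 region the SD was 9.19 points in ovaries and 0.750 in testes (exact permutation p = 0.000119, adjusted p = 0.00107). In the chromosome 19 region it was 3.47 against 0.505 points (exact permutation p = 0.00140, adjusted p = 0.00628). Testes were near 95% at most CpGs of these regions, which compresses their SD in percent. On the log-odds scale neither region passed (chromosome 18 SD 0.462 against 0.189, exact permutation p = 0.0392, adjusted p = 0.176; chromosome 19 SD 0.413 against 0.142, exact permutation p = 0.115, adjusted p = 0.345), so the call depends on the scale. These are also the regions with lower coverage in ovaries. In the chromosome 10 region the SD was 6.54 against 5.56 points (exact permutation p = 0.756), and in the chromosome 24 region 5.01 against 4.45 points (exact permutation p = 0.995).

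Within a sex, no pair of regions had correlated levels after adjustment over 42 pairs (1 pair under an unadjusted p of 0.05 by Pearson's r). With all positions, the closest relation joined the chromosome 10 and chromosome 23 regions. In testes r was 0.680 (permutation p = 0.0295, adjusted p = 0.797) and rho was 0.806 (permutation p = 0.00709, adjusted p = 0.298), with r = 0.689 after leaving out the 2 fish farthest from the median. In ovaries r was 0.607 (exact permutation p = 0.0830, adjusted p = 0.797) and rho was 0.783 (exact permutation p = 0.0172, adjusted p = 0.362), with r = 0.691 after leaving out such fish. This relation rested on low-coverage positions: without them r was 0.165 in testes (permutation p = 0.657) and 0.443 in ovaries (exact permutation p = 0.233). The first chromosome 5 region entered no correlation because its values fell into separate groups.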

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

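The test of other splits of the fish over all CpGs was planned; every other test in this part was chosen after the result it bears on had been seen. Across 84 sets of values (regions, named CpGs and total calls, each in 1 sex), 17 held a fish far from the rest, where chance gives about 5% of sets; CpGs of a region are not independent, so these form few patterns. For the count of 71 CpGs, 1 of 100 splits of the 19 fish into 9 and 10, the real one, gave as many, so chance alone is an unlikely source of it. The test sampled 100 of the 92378 splits and treats the fish as independent, which they may not be in the first chromosome 5 region. The highest other split gave 68 and had 8 of the 9 ovaries together. Without the first chromosome 5 region, where fish agree in pairs, the real split gave 47 of 126 CpGs, the highest other 45, and again 1 of the 100 splits gave as many.

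In the first chromosome 5 region testis 9 stood apart at 42.5% from the other testes, whose highest was 6.86%, and so did its CpGs 44945108 (79.0%), 44945105 (70.1%), 44944888 (22.02%), 44945118 (61.0%) and 44945152 (51.3%). Testis 9 lay closer to the other testes than to the ovaries in all 4 of the chromosome 10, 18, 19 and 24 regions. These regions were chosen for separating the sexes as labelled, testis 9 included, so the count itself is no test. A mislabelled fish is argued against by the level on chromosome 18. There testis 9 had 79.9%, the other testes 77.9% to 80.6% and the ovaries 20.1% to 46.1%. Ovarian tissue or DNA in the sample is argued against too: the share of ovary needed would bring its chromosome 18 level to 38.8%, and it was 79.9%. A candidate explanation is amplified product of this region alone that ovary 11 and testis 9 share, since their counts differed by a chi-square per CpG of 0.978, within sampling noise. They differed by 9.58 on chromosome 23, 14.5 in the second chromosome 5 region and 15.7 on chromosome 3, where the sexes overlap. These values are beyond noise but below the medians of all pairs of fish there (20.4, 26.3 and 22.55). The agreement of 8 pairs within noise here goes with it. So does the loss of reads at 44944798 in ovary 1 and its partner testis 4 only (52.3% and 53.4% of the region's median coverage, against at least 97.0% at every CpG of the other fish). Other causes of that loss, a variant that both fish carry among them, were not tested. Whether sharing arose at amplification, pooling or read assignment stays open, and so does which fish of a mixed pair the product came from.

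In the chromosome 18 region testis 14 was lowest of the testes at 77.9%, as it was at 39636523 (93.1%), 39636171 (93.4%), 39636218 (93.8%) and 39636412 (92.0%), and it was highest of the testes at 21640721 on chromosome 24 (5.49%). On chromosome 3, ovary 11 had the lowest region mean of the ovaries (0.273%) and testis 3 the highest of the testes (0.667%). At 54607226, ovary 6 stood out at 0.472% and testis 14 at 5.26%, the latter from 19 reads. At 67992853 in the second chromosome 5 region ovary 11 had 1.26%.

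Reads outside the tested regions showed methylation in testis 10. A chromosome 16 stretch (54465006 to 54465383, 19 CpGs) had 504 reads there and a mean of 86.4%, where a count of 0 allows up to 0.595%; the other fish had at most 12 reads and 69.4% methylated over all their calls. A chromosome 3 stretch (18047116 to 18047338, 6 CpGs) had 54 reads in testis 10 and a mean of 81.9%, where a count of 0 allows up to 5.56%; the other fish had at most 6 reads and 47.1% methylated over all their calls.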

How the results depend on the processing

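Leaving out low-coverage positions, CpGs with grouped testis values or the first chromosome 5 region, using the log-odds scale, and counting agreeing or nearest fish of a sex once, with mixed pairs left out, were chosen after seeing the data. The other settings were planned. The differences in the chromosome 5 (first region), 10, 18, 19, 23 and 24 regions kept their direction under every setting run for regions and passed the threshold with 1 exception, each fish left out included. That was the setting in which the same-sex nearest pairs of the first chromosome 5 region were counted once and its 4 mixed pairs left out. The region then differed by 39.5 points over 3 samples per sex (exact permutation p = 0.1, the smallest possible there). Otherwise the highest adjusted p was 0.0457 for chromosome 23 and 9.26e-05 for chromosomes 10, 18, 19 and 24. For the first chromosome 5 region it was 0.0425 with 1 fish left out, and 0.0429 with agreeing fish counted once and the 3 mixed pairs among them left out. Leaving out mixed pairs removes fish whose levels go against the difference, so those settings do not bear on it. The count of 71 CpGs became 44 with fish weighted by coverage (11 higher in ovaries), 131 with Fisher's exact test on pooled reads, which ignores the spread between fish (60 higher), and 47 without the first chromosome 5 region; with a coverage minimum of 100 it was 52 (17 higher) and with limma 76. Leaving out each fish gave 51 to 72, the lowest without ovary 11 or ovary 15. With medians over CpGs the difference reversed in the chromosome 3 region (-0.0271 points) and the second chromosome 5 region (-0.315 points); single high CpGs enter the mean and not the median. Leaving out each fish moved these differences from 0.0850 to 0.154 and from -0.0121 to 0.0340 points. Chromosome 18 and 19 stayed more variable in ovaries at a coverage minimum of 100 but did not pass on the log-odds scale (mean absolute deviation higher by 0.228 and 0.168), where the direction reversed on chromosomes 10 (-0.243), 23 (0.0335) and 24 (-0.0598) without passing. At a coverage minimum of 100 no correlation passed (36 pairs; that of chromosomes 10 and 23 fell to r = 0.165 in testes). The setting that drops positions where the reference has no CpG was not run, because the GRCz11 sequence was not used here, and a coverage minimum of 100 gave no value for chromosome 7. No paired analysis was possible because each fish has a number of its own.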

Other observations

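All tests of explanations in this part were chosen after the result was seen. In 2 of the 3 regions near 0, the level typical of a CpG was lower in ovaries although region means were close. Without low-coverage positions, the median over CpGs within a fish averaged 0.315% ± 0.124 (SD, n = 9) in ovaries and 0.611% ± 0.0481 (SD, n = 10) in testes on chromosome 23 (exact permutation p = 8.66e-05). In the second chromosome 5 region it averaged 0.291% ± 0.0850 (SD, n = 9) and 0.601% ± 0.0856 (SD, n = 10) (exact permutation p = 2.17e-05). On chromosome 3 it was 0.334% against 0.365% (exact permutation p = 0.677). Single CpGs stood high on chromosome 3: 5 values in 4 ovaries exceeded 5%, up to 12.3% at 54607290 in ovary 15 from 12529 reads, and 2 in testis 14, from 19 reads each. Their number per fish gave no difference between the sexes (exact permutation p = 0.336), and no value exceeded 5% on chromosome 23 (highest 2.76%) or in the second chromosome 5 region (highest 3.74%).

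Unconverted cytosines and base errors add to a level; more of them in testis libraries, common to all regions of a library, could give this difference, but in all 3 regions. Chromosome 23 minus the mean of both other regions still differed between the sexes (exact permutation p = 0.00244, and p = 0.00604 with medians). Part of the difference in means came from chromosome 3, which was higher in ovaries (0.605% against 0.493%) and held the single high CpGs. Chromosome 23 minus chromosome 3 differed in the medians by -0.264 points (exact permutation p = 0.000217). This argues against an error common to all regions, but it rests on chromosome 3 alone. The medians of chromosome 23 and the second chromosome 5 region differed alike (exact permutation p = 0.799), so an error in these 2 regions alone stays open. Fewer template molecules amplified from ovary libraries might give low typical values with single high CpGs. The SD over CpGs within a fish was higher in ovaries with an exact permutation p under the threshold in 2 of the 3 regions (0.541 against 0.178 points on chromosome 23 and 0.698 against 0.232 in the second chromosome 5 region, both p = 1.08e-05, the smallest the permutations can give). On chromosome 3 it was 1.12 against 0.518 points (exact permutation p = 0.0579, and p = 0.0281 at a coverage minimum of 100), so fewer templates cannot be told apart from other causes either.

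At 44956872 on chromosome 10 and 21640811 on chromosome 24 the testes fell into separate groups, 7 at or below 49.1% and 3 at or above 81.5% at the former, 3 at or below 3.29% and 7 at or above 40.4% at the latter. A C-to-T variant, read as unmethylated, would bring the level at the chromosome 10 CpG near 0.5 of that of the nearest CpG in fish with 1 copy and leave it alike in fish with none. The CpG was picked for a gap between its testis values, so the ovaries were taken as the test. That choice did not fix the testis ratios: 7 testes had ratios of 0.483 to 0.502, and 2 had at least 0.85. Of the ovaries, 7 of 9 had a ratio within 0.1 of 0.5 (5 ovaries) or at least 0.85 (2 ovaries). Ovary 13 (0.826) and ovary 17 (0.836) had neither, like testis 4 (0.838). The ovary ratios formed 2 groups, from 0.435 to 0.555 and from 0.826 to 0.926, so ovaries 13 and 17 missed the bound of 0.85 narrowly. A variant cannot be told apart from a difference in methylation here, because 2 of 9 ovaries outside the bounds are too few to decide. At the chromosome 24 CpG 7 of 10 testes lay more than 10 points above the nearest CpGs. A lost C cannot raise a level, but the CpG 21640666, whose testis values form no groups, also stood above its nearest CpGs (20.3% against 7.58%), so a variant stays open there. A variant at other bases was not tested.

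If 1 cell type whose share varies between ovaries set all 4 regions that separate the sexes, chromosome 10, 18 and 19 levels would rise together and chromosome 24 levels fall. Across the 9 ovaries 3 of the 6 pairs had r of the opposite sign, but none of the 6 values of r passed (the lowest exact permutation p was 0.101, r = -0.583 for chromosomes 10 and 24, adjusted p = 0.797). Without low-coverage positions that pair had r = -0.730, in the direction such a share predicts (exact permutation p = 0.0268, adjusted p = 0.544). After leaving out the 2 fish farthest from the median, r was -0.487 without those positions and 0.000956 with all positions. A single share can thus be neither supported nor excluded with 9 ovaries.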
